A study of Mus musculus with 6 samples.

How the data were processed

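RNA of sorted mouse LSK and LK cells, 3 samples of each, was amplified with a linear method, labelled with biotin and hybridised to an Affymetrix mouse expression array, per the labels' protocols. The deposited values are probe set intensities on a linear scale, made with RMA in the affy package under R 2.11.0, per the submitters' processing notes. RMA corrects the background, normalises the arrays to each other by quantiles and summarises the probes of a set, so the arrays have similar distributions and a shift of all genes would not be seen. The authors' scan files and detection calls are not analysed here, and log2 values near 3 lie at the lower end of the range. The fold changes of genes at that level are therefore compressed.

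The table held 45101 probe sets. The 64 control probe sets were left out of the tests and used as measures of quality. Of the other 45037, 34945 carried exactly 1 gene symbol in the platform annotation, 932 carried several and 9160 were not listed in the annotation used. Symbols were updated through the gene identifier in a RefSeq table of assembly GRCm38.p6, which matched 34741 of the 34945, and no coordinates were taken from it, since the array files name no build. Each of 18193 genes was represented by its probe set with the highest mean log2 intensity, and 9010 genes had more than 1. For 21 of the genes past the threshold another probe set of the gene differed the opposite way at an unadjusted p under 0.05. Among the named genes, 5 are represented by a probe set whose suffix marks possible cross-hybridisation (Alas1, C1qb, Dntt, Ndn and Zg16) and 4 by a probe set shared by several transcripts (Hdc, Hnf4a, Hoxa3 and Rfc4).

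Log2 intensities of LSK and LK were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, population as the only term), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Folds are the higher population over the lower. The SD and SE are on the log2 scale, and SD is over 3 arrays. A total of 26 gene lists were tested with camera at its preset correlation of 0.01, adjusted over the lists, and 442 of their 485 genes were measured; 6 genes stand in more than 1 list. With a correlation estimated for each list, which reached 0.73, 0 of the 16 lists past the threshold held (4 lists at an unadjusted p under 0.05). This setting also limits camera to the few degrees of freedom of 6 arrays. Lists with an estimated correlation near 0 were lost too, such as HoxA and HoxB (-0.036, camera adjusted p from 0.000252 to 0.133) and adhesion (-0.017, from 0.0319 to 0.262). The loss therefore does not measure the correlation among members alone. The test fry called 14 lists, but it asks another question. It tests whether members differ at all, and camera whether they differ more than the other genes. The design, the lists and the rule for named genes were set before the data were examined. The rule names Msi1, Msi2 and the sort gate genes, the 6 genes with the largest log2 difference in each direction among those past the threshold whose populations do not overlap, and for each list the 2 members with the largest difference past the threshold, with the largest one of the opposite direction, or the member with the lowest p where none passed. It gave 56 genes. Celf2, Zfp36l2, Hoxa5, Hoxa9, Hoxb3, Il12a, Satb1, Cd34, Cd44, Tfrc, Fech, Abcb10, Mcm2, Idh3a, Ndufv1, Cox6c, Nop2, Dkc1, Mybbp1a, Pdk1, Hspa1a, Hspa1b, Hsph1 and Dnajb1 were added after their values were seen, to complete short counts or to show members opposite to their list, as were the genes in the other observations that the rule does not name.

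The labels number the samples 1 to 3 in both populations without saying what the number stands for. Samples with the same number deviated together: the correlation across genes of their deviations from the population means was 0.42, 0.43 and 0.27, against at most 0.04 between different numbers, and 6 of 6 arrays were closest to the array of their own number. Deviations within a population sum to 0, so high values for the same number lower those between different numbers, and the contrast is partly built in. On this limited basis the numbers were taken to pair the samples, a pairing that comes from the data. A fit with the number as a block stands beside results whose call it changes or whose count it moves by more than 1.5 times. The labels do not say that the arrays come from separate animals, so the p-values measure the spread between these samples, part of which may be technical. No pair of arrays held identical values (0 of 15).

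The alternatives were the replicate block, renewed quantile or cyclic loess normalisation, a filter on dim probe sets, other ways to represent a gene, other variance models, array weights, a fold minimum, other list tests and leaving out each array in turn. The replicate 2 arrays left out of both populations, the 3' to 5' difference as a covariate, replicate 2 against the others as a batch and the estimated correlation together with the block were chosen after seeing the data. The procedure was tested on simulated data for the LSK and LK comparison, with 18193 genes of which 200 were changed in each of 5 runs. It recovered 42.9% of 2-fold, 80.7% of 4-fold and 96.2% of 16-fold changes, and 5.5% of its calls were unchanged genes. The simulated genes were independent of each other and had no deviation shared by replicate number, unlike the real arrays. These percentages therefore need not hold for the real data.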

Results

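RNA was measured in 2 blood-forming cell populations sorted from wild-type C57BL/6 mouse by flow cytometry. Both were low in lineage markers and carried the receptor Kit. LSK cells also carried the surface protein Sca-1 and hold the stem cells and multipotent progenitors, and LK cells lacked Sca-1 and hold the committed progenitors. Each population had 3 arrays, and the number of arrays limits the precision of every value. The median probe set intensity lay between 7.88 and 8.49 on the 6 arrays. The upper quartile was 22.0 and 20.7 on the replicate 2 arrays of LSK and LK, and 24.2 to 25.7 on the others. Across genes, which are not independent replicates, arrays of the same population correlated with r from 0.972 to 0.986 and arrays of different populations with r from 0.941 to 0.969. The first principal component held 57.4% of the variance and separated the populations. The second held 21.6% and set the replicate 2 arrays (-31.7 in LSK and -41.2 in LK) apart from the others (7.25 to 29.8). The mean log2 difference between the 3' and 5' control probe sets of Actb and Gapdh, a joint measure of RNA integrity and amplification in which a higher value means more 3' bias, was 2.64 ± 0.56 (SD, n = 3) in LSK and 3.53 ± 0.36 (SD, n = 3) in LK. A two-sided exact permutation test gave p = 0.2 for this difference, and 0.1 is the smallest p that 3 arrays against 3 allow. The value was higher in LK in 3 of 3 pairs of arrays with the same number (exact sign-flip test p = 0.25, the smallest that 3 pairs allow). Kit, which both sort gates used, had a log2 intensity of 8.55 ± 0.39 in LSK and 7.74 ± 0.35 in LK, and did not pass the threshold (1.75-fold, limma adjusted p = 0.124, 0.0185 with the replicate number as a block). The gene for Sca-1 is not analysed here.

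The title of the series names Musashi 2, an RNA-binding protein, so its transcript was compared first. Msi2 was higher in LSK than in LK cells, with a log2 intensity of 12.17 ± 0.24 (SD, n = 3) in LSK and 9.89 ± 0.29 (SD, n = 3) in LK. The log2 difference was 2.28 (SE 0.20), or 4.86-fold, with a limma adjusted p of 0.00331, and the level was higher in LSK in 3 of 3 pairs of arrays with the same number. Of the 8 Msi2 probe sets, 5 were past the threshold over all probe sets, with log2 differences from 2.00 to 2.74, and the other 3 had means under a log2 of 4 in both populations. Msi1, its paralog, had log2 intensities of 3.52 ± 0.16 and 3.49 ± 0.43, near the lower end of the array's range, with a log2 difference of 0.03 (adjusted p = 0.965), and none of its 3 probe sets was past the threshold. Among 14 measured Musashi and other stem-cell RNA-binding protein genes, 4 were higher in LSK, 0 lower and 10 not past the threshold, and 4 were higher when adjusted over the list alone. Besides Msi2 these were Rbpms (7.29-fold, adjusted p = 0.00879), Celf2 (1.84-fold, adjusted p = 0.0397) and Zfp36l2, an mRNA decay factor (1.92-fold, adjusted p = 0.0184). The list as a whole did not pass (median log2 difference 0.06, camera adjusted p = 0.0547), and passed without LSK replicate 1 (0.048), LK replicate 2 (0.0294) or LK replicate 3 (0.0331), where 2, 3 and 1 members were past the threshold. The median was 0.010 without LSK replicate 1, 0.017 without LSK replicate 2, 0.15 without LSK replicate 3, 0.035 without LK replicate 1 and 0.16 without LK replicate 2. The list also passed with fry (0.0024), trend and robust variances (0.0207), averaged probe sets (0.0214), renewed quantile (0.0436) or loess normalisation (0.0463) and the covariate named below (0.0344). Without LSK replicate 2 there were 2, and Rbpms was lost without LK replicate 3 (adjusted p = 0.0502), Zfp36l2 without LSK replicate 1, LSK replicate 2 or LK replicate 3 (up to 0.0766) and Celf2 in each fit without 1 array except that without LSK replicate 3 (up to 0.125). With the 3' to 5' difference of each array as a covariate, Msi2 had a log2 difference of 1.92 and an adjusted p of 0.101.

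Notch signalling has been linked to Musashi proteins through Numb, an inhibitor of Notch. Notch1, a receptor of the pathway, was 3.14-fold higher in LSK (log2 difference 1.65, SE 0.17, adjusted p = 0.00487). It was the only one of 21 measured Notch pathway genes past the threshold over all genes, and 3 were higher and 1 lower when adjusted over the list alone. The list did not pass camera (adjusted p = 0.467), and its median log2 difference of -0.04 lay opposite to its mean of 0.08 and to the test's upward direction. The median lay above 0 without LSK replicate 1 (0.0080), LSK replicate 2 (0.084) or LK replicate 2 (0.0084). With the replicate number as a block, 3 members were higher and 1 lower. Without LSK replicate 2 there were 2 higher, and without LSK replicate 3 also 1 lower.

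Over the whole array, 1225 of 18193 genes differed between the populations in limma, 699 higher and 526 lower in LSK. The 6 genes with the largest measured differences toward LSK were Fscn1, which encodes the actin-bundling protein fascin (57.2-fold), the myosin light chain gene Myl10 (38.5-fold), Dntt, the template-independent DNA polymerase of lymphoid progenitors (37.0-fold), the nuclear receptor gene Hnf4a (32.4-fold), Mecom, a transcription factor needed by stem cells (29.2-fold), and the imprinted gene Ndn (29.1-fold). Toward LK they were Ermap, an erythroblast membrane protein gene (81.4-fold), the carbonic anhydrase gene Car1 (66.7-fold), the metallothionein gene Mt2 (35.0-fold), Pklr, the red cell pyruvate kinase gene (29.0-fold), Klf1, the erythroid transcription factor (27.8-fold), and Zg16 (25.4-fold). In 8 of these 12 genes (all except Dntt, Hnf4a, Mecom and Car1), as in 288 of the 1225, the lower population had a mean log2 under 4, near the lower end of the range, so their folds are limited by it and their order has no meaning. Only 1 of 4 Hnf4a, 1 of 3 Mecom and 1 of 3 Pklr probe sets differed in the gene's direction at an unadjusted limma p under 0.05. For Fscn1 this held for 2 of 4, for Dntt 3 of 3, for Ndn 5 of 8 and for Zg16 2 of 3. No probe set of these genes differed the opposite way at that p. The adjusted p of the 12 genes lay between 0.000285 for Fscn1 and 0.00896 for Pklr. Each separated the 3 arrays of one population from the 3 of the other, as the rule that named them requires. The median fold was 2.73 among the genes higher in LSK and 2.40 among those lower, and 903 genes differed by 2-fold or more (529 higher, 374 lower). All 1225 genes had groups without overlap, as did 28.0% of the genes tested, against 10% that chance gives. With the replicate number as a block, 2617 genes differed (1278 higher, 1339 lower), of which 1221 were among the 1225. The count was 322 without LSK replicate 1, 679 without LSK replicate 2, 768 without LK replicate 1, 767 without LK replicate 2, 306 without LK replicate 3, 537 without both arrays numbered 2, and 25 with the 3' to 5' difference as a covariate. With this covariate the log2 differences of the 1225 genes kept their sign and had a median ratio of 0.86 to the earlier ones while the standard errors had a median ratio of 1.54.

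**Figure D1:**
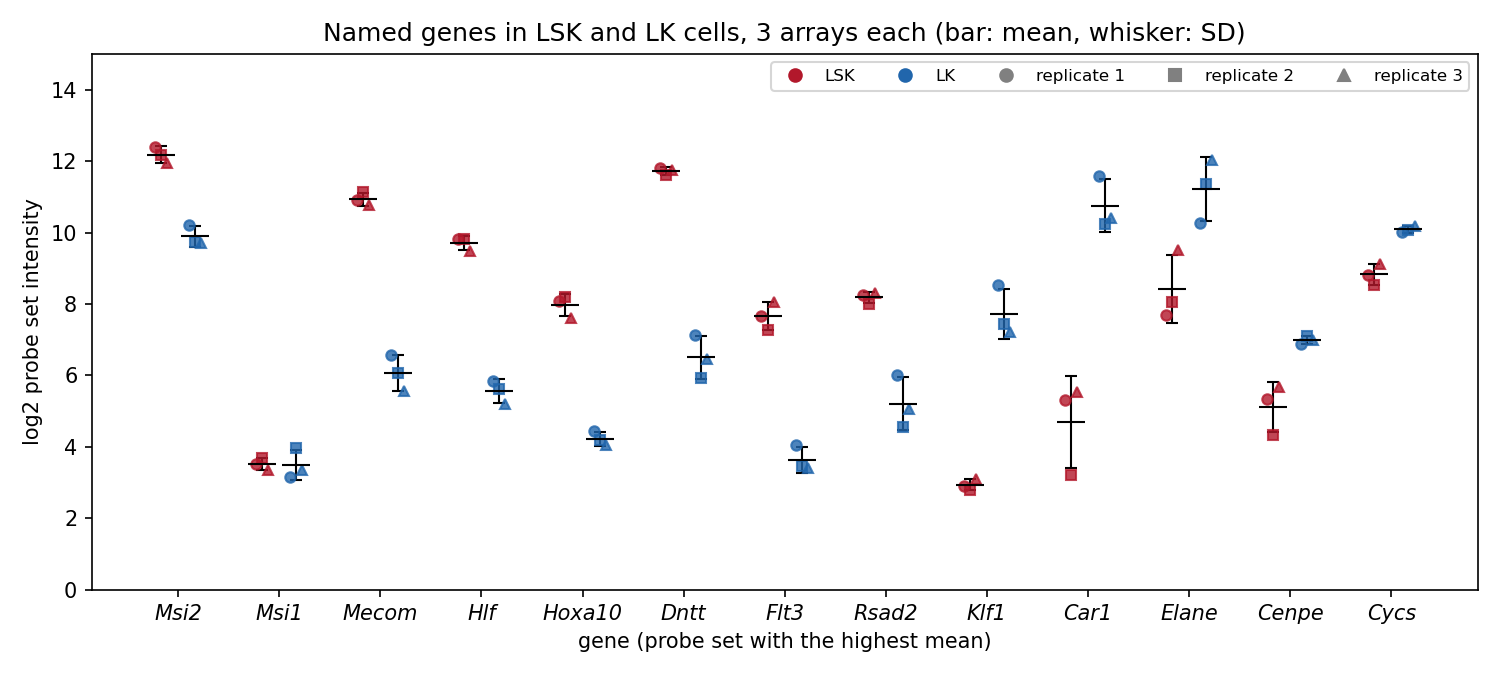
Log2 probe set intensity (vertical axis) of 13 named genes (horizontal axis) on each of the 6 arrays, with LSK in red, LK in blue, the symbol giving the replicate number, bars the mean and whiskers the SD of 3 arrays. Msi2 had a mean of 12.17 in LSK and 9.89 in LK, whereas Klf1 had 2.93 and 7.73.

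Gene lists fixed in advance described what the populations expressed, and 16 of the 26 lists passed camera, 9 toward LSK and 7 toward LK. The 9 other splits of the 6 arrays into 3 and 3 gave 4 to 12 lists past the threshold, so a call of a list alone is weak evidence. In the real comparison, stem cell genes gave the lowest p. Of 20 measured, 11 were higher in LSK, 0 lower and 9 not past the threshold (15 higher and 0 lower when adjusted over the list alone). Mecom reached a log2 intensity of 10.93 ± 0.18 in LSK against 6.06 ± 0.50 in LK, and Hlf, another transcription factor of stem cells, 9.70 ± 0.19 against 5.57 ± 0.33 (17.6-fold, adjusted p = 0.000629). The list's median log2 difference was 1.31 (camera adjusted p = 2.78e-14, adjusted p = 0.133 with an estimated correlation). It held 7 such genes without LSK replicate 1 and 5 without LK replicate 3. In the HoxA and HoxB clusters, which encode homeobox transcription factors of early progenitors, 5 of 14 measured genes were higher and 0 lower, also when adjusted over the list alone: Hoxa10 (13.4-fold), Hoxa3 (11.3-fold), Hoxa9 (4.68-fold), Hoxb3 (3.68-fold) and Hoxa5 (2.91-fold), with adjusted p from 0.000597 for Hoxa3 to 0.00879 for Hoxa5. The median of this list was 0.27 (camera adjusted p = 0.000252, adjusted p = 0.133 with an estimated correlation), and 0.16 without LSK replicate 3.

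Adhesion and niche receptor genes passed toward LSK with a median log2 difference of 0.15 (camera adjusted p = 0.0319, adjusted p = 0.262 with an estimated correlation). Of 18 measured, 4 were higher, 0 lower and 14 not past the threshold, and 6 were higher when adjusted over the list alone. They were Angpt1, a ligand of the receptor Tie2 (5.04-fold, adjusted p = 0.0123), the integrin ligand Icam1 (3.70-fold, adjusted p = 0.0286), Cd34 (2.57-fold, adjusted p = 0.0111) and the hyaluronan receptor Cd44 (1.70-fold, adjusted p = 0.0353). The list did not pass with the replicate number as a block (adjusted p = 0.0505, 6 higher and 1 lower), with array weights (0.0647) or without LSK replicate 3 (0.0994). The median was 0.052 without LSK replicate 2 and 0.098 without LK replicate 2. The count of members was 0 without LSK replicate 1 or LK replicate 3 and 2 without LK replicate 2. Angpt1 and Cd34 were lost without LSK replicate 1 or LK replicate 3 (adjusted p up to 0.0591 and 0.0586), Icam1 in each fit without 1 array except that without LSK replicate 2 (up to 0.103) and Cd44 in each except that without LSK replicate 3 (up to 0.121).

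The list of lymphoid-primed progenitor genes also passed toward LSK. Of 14 measured, 5 were higher, 0 lower and 9 not past the threshold, and 7 were higher when adjusted over the list alone. Dntt had a log2 intensity of 11.72 ± 0.10 in LSK and 6.51 ± 0.60 in LK (adjusted p = 0.000738), and Wfdc17 9.55 ± 0.41 and 4.90 ± 0.44 (25.1-fold, adjusted p = 0.00117). The others were Flt3, a cytokine receptor of multipotent progenitors (16.2-fold, adjusted p = 0.00127), Il12a (5.14-fold, adjusted p = 0.000685) and the chromatin organiser Satb1 (3.36-fold, adjusted p = 0.00154). The median log2 difference was 0.48 (camera adjusted p = 2.61e-08, adjusted p = 0.133 with an estimated correlation).

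Among 11 measured MHC class II and dendritic cell genes, 2 were higher, 0 lower and 9 not past the threshold, and 6 were higher when adjusted over the list alone. These were Flt3 and Cd74, the invariant chain of MHC class II (4.60-fold, adjusted p = 0.0417). The list's median was 0.80 (camera adjusted p = 6.84e-05, adjusted p = 0.166 with an estimated correlation), and 5 members were higher with the replicate number as a block. Cd74 was lost in each fit without 1 array except that without LK replicate 1 (adjusted p up to 0.117), which left 1 member. None of 12 measured B-cell genes and none of 14 T-cell and NK-cell genes passed limma, 0 over the list alone and 0 at an unadjusted p under 0.05 in both lists. The lowest p in these lists belonged to Ms4a1, which encodes CD20 (log2 2.87 ± 0.06 in LSK and 3.50 ± 0.56 in LK, adjusted p = 0.235), and Cd3d, a T-cell receptor subunit (2.92 ± 0.05 and 2.67 ± 0.07, adjusted p = 0.287). The B-cell list had a median of -0.003 and a mean of 0.04 (camera upward, adjusted p = 0.954, with 1 gene lower without LK replicate 1), and the T-cell and NK-cell list a median of 0.09 (adjusted p = 0.344). The B-cell median was 0.051 without LSK replicate 2, 0.070 without LK replicate 2, 0.027 without LK replicate 3 and from -0.086 to -0.021 without each other array. The T-cell and NK-cell median was 0.17 without LSK replicate 1 and 0.037 without LSK replicate 2.

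Interferon-stimulated genes were higher in LSK, 10 of 23 measured, with 0 lower and 13 not past the threshold, and 13 higher when adjusted over the list alone. Rsad2, the antiviral protein viperin, had a log2 intensity of 8.18 ± 0.16 in LSK and 5.20 ± 0.74 in LK (7.88-fold, adjusted p = 0.00742), and the GTPase gene Iigp1 5.29 ± 0.57 and 2.82 ± 0.06 (5.57-fold, adjusted p = 0.00657). The median log2 difference of the list was 1.11 (camera adjusted p = 2.5e-09, adjusted p = 0.262 with an estimated correlation), and the count was 4 without LSK replicate 1 and 5 without LK replicate 3. Immediate early and heat-shock genes, which dissociation and sorting can induce, had a median of 1.11 (camera adjusted p = 6.57e-05, adjusted p = 0.366 with an estimated correlation, fry adjusted p = 0.13), and 0.71 without LSK replicate 3. Of 18 measured, 2 were higher, 0 lower and 16 not past the threshold (7 higher when adjusted over the list alone, 9 higher and 1 lower with the replicate number as a block). They were Ier3 (5.83-fold, adjusted p = 0.0297) and Jun (2.99-fold, adjusted p = 0.0471). Among its 4 heat-shock genes, Hspa1a, Hspa1b and Hsph1 lay below 0 (log2 differences -1.96, -0.27 and -0.28) and Dnajb1 above (0.61), none past the threshold. The member lower with the block was Hspa1a (adjusted p = 0.0481). Without LSK replicate 2 there were 4 higher and in each other fit without 1 array 0, with Hspa1a lower without LSK replicate 3. Jun was lost in all 6 of these fits (adjusted p up to 0.146) and Ier3 in all except that without LSK replicate 2 (up to 0.0896).

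The erythroid list passed toward LK. Of 22 measured, 0 were higher, 7 lower and 15 not past the threshold (1 higher and 13 lower when adjusted over the list alone, 1 and 12 with the replicate number as a block). Ermap had a log2 intensity of 3.67 ± 0.64 in LSK and 10.02 ± 0.66 in LK, Car1 4.69 ± 1.28 and 10.75 ± 0.74, and Klf1 2.93 ± 0.15 and 7.73 ± 0.71. The list had a median of -1.54 (camera adjusted p = 9.1e-07, adjusted p = 0.265 with an estimated correlation), and 4 of its genes passed without LK replicate 3. Haem synthesis and iron import genes had a median of -0.89 (camera adjusted p = 1.42e-07, adjusted p = 0.262 with an estimated correlation), with 0 of 14 measured higher, 5 lower and 9 not past the threshold. The number lower was 11 when adjusted over the list alone and 9 with the replicate number as a block. Alas1, an isoform of the first enzyme of haem synthesis, was 9.91-fold lower in LSK (adjusted p = 0.0291) and the later enzyme Cpox 5.22-fold (adjusted p = 0.00469). The other 3 were the transferrin receptor Tfrc (2.94-fold, adjusted p = 0.0139), the ferrochelatase gene Fech (2.42-fold, adjusted p = 0.0361) and the mitochondrial transporter gene Abcb10 (1.86-fold, adjusted p = 0.0288). The number lower was 2 without LSK replicate 1, 2 without LSK replicate 2, 3 without LSK replicate 3 and 1 without LK replicate 3, and Alas1 was lost without LSK replicate 1, LSK replicate 2, LK replicate 2 or LK replicate 3 (adjusted p up to 0.109). Tfrc was lost without LK replicate 3 (0.0629), Fech without any LSK array or LK replicate 3 (up to 0.109) and Abcb10 in each fit without 1 array except that without LK replicate 2 (up to 0.112).

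The list of primary granule and granulocyte-monocyte progenitor genes passed toward LK as well. Of 17 measured, 0 were higher, 7 lower and 10 not past the threshold, and 12 were lower when adjusted over the list alone. Elane, the neutrophil elastase gene, had a log2 intensity of 8.42 ± 0.95 in LSK and 11.22 ± 0.89 in LK (log2 difference -2.81, adjusted p = 0.041), and the annexin gene Anxa3 5.60 ± 1.23 and 9.09 ± 0.88 (log2 difference -3.49, adjusted p = 0.0343). The median was -1.84 (camera adjusted p = 7.43e-08, adjusted p = 0.297 with an estimated correlation). Without LSK replicate 1, LSK replicate 2, LK replicate 2 or LK replicate 3 the count was 0, with adjusted p up to 0.13 for Elane and 0.123 for Anxa3, and fry did not call the list (adjusted p = 0.0554). Mast cell, basophil and eosinophil genes had 0 higher, 2 lower and 11 not past the threshold of 13 measured (3 lower when adjusted over the list alone, 4 with the replicate number as a block), namely the histidine decarboxylase gene Hdc (11.8-fold, adjusted p = 0.0122) and Ms4a2, a subunit of the IgE receptor (3.55-fold, adjusted p = 0.0288). Their list did not pass (median -0.13, camera adjusted p = 0.0593), but did without LSK replicate 3 (0.0111), LK replicate 1 (0.0392) or LK replicate 2 (0.0264), with array weights (0.0135) and with trend and robust variances (0.0313). Its median was -0.23 without LK replicate 2. Hdc was lost without LSK replicate 1 or LK replicate 3 (adjusted p up to 0.0586), and Ms4a2 without these, LSK replicate 2 or LK replicate 1 (up to 0.101), so that 0 members passed without LSK replicate 1 or LK replicate 3 and 1 without LSK replicate 2 or LK replicate 1.

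Secondary granule and mature neutrophil genes, markers of a mature cell that a progenitor gate could hold, went the other way (median 0.57, camera adjusted p = 0.00419, adjusted p = 0.366 with an estimated correlation). Of 13 measured, 1 was higher, 0 lower and 12 not past the threshold, 2 were higher when adjusted over the list alone, and 7 were higher with the replicate number as a block. Padi4, an enzyme that citrullinates histones, was 2.78-fold higher in LSK (adjusted p = 0.0141) and was lost without LK replicate 3 (adjusted p = 0.0605), and 2 genes passed without LSK replicate 2. The median was 0.24 without LSK replicate 3 or LK replicate 2, 0.87 without LSK replicate 2 and 0.95 without LK replicate 3. The list did not pass without LSK replicate 3 (0.0546) or LK replicate 1 (0.0587), with array weights (0.0787) or with fry (0.143). Monocyte and macrophage genes had a median of -0.50, or -0.19 without LSK replicate 1, and did not pass (camera adjusted p = 0.254). Of 16 measured, 2 were higher, 0 lower and 14 not past the threshold (2 higher and 3 lower when adjusted over the list alone, 2 and 5 with the replicate number as a block). The higher genes were the transcription factor Klf4 (3.66-fold, adjusted p = 0.00627) and the complement gene C1qb (2.84-fold, adjusted p = 0.0108), which was lost without LSK replicate 1 or LK replicate 3 (up to 0.0571), leaving 1. C1qb lay near the lower end of the range (log2 3.84 ± 0.21 in LSK and 2.34 ± 0.31 in LK). The complement genes C1qa and C1qc also lay there, with log2 differences of 0.15 and 0.05, neither past the threshold. Without LSK replicate 3 the list passed downward (0.038), with 3 members lower.

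Megakaryocyte and platelet genes did not pass as a list, with a median of -0.02 opposite to a mean of 0.16 and an upward test (camera adjusted p = 0.837). The median was 0.0084 without LK replicate 1, -0.0028 without LK replicate 3, -0.034 without LSK replicate 2 and -0.046 without LSK replicate 3. Of 18 measured, 2 were higher, 0 lower and 16 not past the threshold (3 higher and 2 lower when adjusted over the list alone, 3 and 1 with the replicate number as a block). They were Gucy1a1, a subunit of soluble guanylate cyclase (8.61-fold, adjusted p = 0.0219), and Selp, which encodes P-selectin (2.65-fold, adjusted p = 0.0397). Gucy1a1 was lost without LSK replicate 1 or LK replicate 3 (adjusted p up to 0.0905) and Selp in each fit without 1 array except that without LSK replicate 3 (up to 0.119), and 1 member was lower without LK replicate 2. Higher members numbered 0 without LSK replicate 1 or LK replicate 3 and 1 without LSK replicate 2 or LK replicate 2. Among 16 measured endothelial and stromal genes, Emcn, the endothelial sialomucin endomucin, was the 1 past the threshold, also over the list alone (3.41-fold higher, log2 4.03 ± 0.42 and 2.26 ± 0.24, adjusted p = 0.0119), and was lost without LK replicate 3 (0.0586). This list had a median of -0.02 and a mean of 0.08 (camera upward, adjusted p = 0.837). Its median was -0.0083 without LSK replicate 1, -0.065 without LSK replicate 2, -0.099 without LK replicate 1, 0.022 without LK replicate 2 and -0.062 without LK replicate 3.

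The lists of mitosis and DNA replication genes passed toward LK. Of 21 measured genes of mitosis, 0 were higher, 7 lower and 14 not past the threshold, and 14 were lower when adjusted over the list alone and 15 with the replicate number as a block. The kinetochore motor gene Cenpe was 3.66-fold lower (adjusted p = 0.0263) and the spindle checkpoint kinase gene Bub1 3.44-fold (adjusted p = 0.00714). The median was -1.23 (camera adjusted p = 7.64e-10, adjusted p = 0.262 with an estimated correlation), and the count was 2 without LSK replicate 1, 4 without LSK replicate 3, 3 without LK replicate 1 and 2 without LK replicate 3. Of 21 measured DNA replication genes, 0 were higher, 3 lower and 18 not past the threshold, with 12 lower when adjusted over the list alone and 11 with the replicate number as a block. They were the origin licensing factor Cdc6 (4.91-fold, adjusted p = 0.0188), the clamp loader subunit Rfc4 (2.42-fold, adjusted p = 0.0188) and the helicase subunit Mcm2 (2.07-fold, adjusted p = 0.0296). The median was -0.76 (camera adjusted p = 4.86e-06, adjusted p = 0.297 with an estimated correlation). The count was 0 without LSK replicate 1, LK replicate 1, LK replicate 2 or LK replicate 3 and 8 without LSK replicate 3. Cenpe, Cdc6 and Rfc4 were lost in the first 4 of these fits (adjusted p up to 0.0982 for Cenpe, 0.0776 for Cdc6 and 0.079 for Rfc4), and Mcm2 in these and without LSK replicate 2 (up to 0.0974).

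Cyclin-dependent kinase inhibitor and FoxO genes, which restrain the cycle, were higher in LSK as a list (median 0.43, camera adjusted p = 0.0015, adjusted p = 0.262 with an estimated correlation). The median was 0.22 without LSK replicate 3, 0.65 without LK replicate 1 and 0.16 without LK replicate 2. Of 15 measured, 2 were higher, 0 lower and 13 not past the threshold (5 higher when adjusted over the list alone, 6 with the replicate number as a block). They were Ccng2, an atypical cyclin that slows the cycle (2.07-fold, adjusted p = 0.0104), and Cdkn1b, which encodes the inhibitor p27 (1.52-fold, adjusted p = 0.0418). Ccng2 was lost without LSK replicate 1 or LK replicate 3 (up to 0.0558), where 0 members passed. Cdkn1b was lost in all 6 fits without 1 array (up to 0.142), and 1 member passed without LSK replicate 2, LSK replicate 3 or LK replicate 2.

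The lists of oxidative phosphorylation and ribosome biogenesis genes passed toward LK. Of 28 measured oxidative phosphorylation and TCA cycle genes, 0 were higher, 5 lower and 23 not past the threshold, with 18 lower when adjusted over the list alone and 16 with the replicate number as a block. They were the electron carrier genes Cyc1 (2.52-fold, adjusted p = 0.0123) and Cycs (2.40-fold, adjusted p = 0.0123), Idh3a (2.38-fold, adjusted p = 0.0169), Ndufv1 (log2 difference -1.08, adjusted p = 0.0339) and Cox6c (1.55-fold, adjusted p = 0.0476). The median was -0.69 (camera adjusted p = 8.34e-09, adjusted p = 0.297 with an estimated correlation). The count was 0 without LSK replicate 1 or LK replicate 3, with adjusted p up to 0.0607 for Cyc1 and 0.0627 for Cycs, 3 without LSK replicate 2, 8 without LSK replicate 3 and 2 without LK replicate 1. Idh3a was lost without LSK replicate 1, LK replicate 1 or LK replicate 3 (up to 0.0767), and Ndufv1 and Cox6c in each fit without 1 array except that without LSK replicate 3 (up to 0.118 and 0.16). Of 23 measured ribosome biogenesis genes, 1 was higher, 4 lower and 18 not past the threshold (2 and 6 when adjusted over the list alone). Mycn, a Myc family transcription factor, was 13.2-fold higher in LSK (adjusted p = 0.0122). The lower genes were Bop1 (3.43-fold, adjusted p = 0.00657), Nop2 (2.42-fold, adjusted p = 0.0104), Dkc1 (1.85-fold, adjusted p = 0.04) and Mybbp1a (1.55-fold, adjusted p = 0.0476). The median of -0.52 gave a camera adjusted p of 0.00189 (adjusted p = 0.262 with an estimated correlation), and the block left 2 higher and 6 lower. Mycn was lost without LSK replicate 1 or LK replicate 3 (up to 0.0605), Nop2 without LSK replicate 1 (0.0513), and Dkc1 and Mybbp1a in all 6 fits without 1 array (up to 0.136 and 0.121), and the lower genes numbered 1 without LSK replicate 1 and 2 without LSK replicate 2, LSK replicate 3, LK replicate 1 or LK replicate 3.

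Glycolysis and cholesterol genes did not pass as lists. Of 15 measured glycolysis genes, 2 were higher, 1 lower and 12 not past the threshold (3 and 4 when adjusted over the list alone, 3 and 3 with the replicate number as a block), with a median of -0.22 (camera adjusted p = 0.498), or -0.14 without LSK replicate 2. The glucose transporter gene Slc2a1 was 2.18-fold higher in LSK (adjusted p = 0.0288), the pyruvate dehydrogenase kinase gene Pdk1 1.99-fold higher (adjusted p = 0.0166) and the hexokinase gene Hk1 3.87-fold lower (adjusted p = 0.0489). Slc2a1 was lost in each fit without 1 array except that without LK replicate 3 (up to 0.103), Hk1 in each except that without LSK replicate 3 (up to 0.124) and Pdk1 without LSK replicate 1, LSK replicate 2 or LK replicate 3 (up to 0.0716). The number of higher glycolysis genes was 0 without LSK replicate 1 or LSK replicate 2 and 1 in the other such fits, and the number lower was 0 without LSK replicate 1, LSK replicate 2, LK replicate 2 or LK replicate 3 and 3 without LSK replicate 3. Of 17 measured cholesterol synthesis and uptake genes, 1 was higher, 0 lower and 16 not past the threshold (1 higher when adjusted over the list alone, 1 higher and 2 lower with the replicate number as a block). Srebf2, the transcription factor of the pathway, was 2.90-fold higher in LSK (adjusted p = 0.0453) and was lost in each fit without 1 array except that without LSK replicate 3 (up to 0.135). The list's median of 0.03 lay opposite to its mean of -0.06, with an upward test (camera adjusted p = 0.991). The median was below 0 without LSK replicate 1 (-0.19) or LK replicate 2 (-0.28), from 0.082 to 0.22 without LSK replicate 2, LK replicate 1 or LK replicate 3 and 0.018 without LSK replicate 3.

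**Figure D2:**
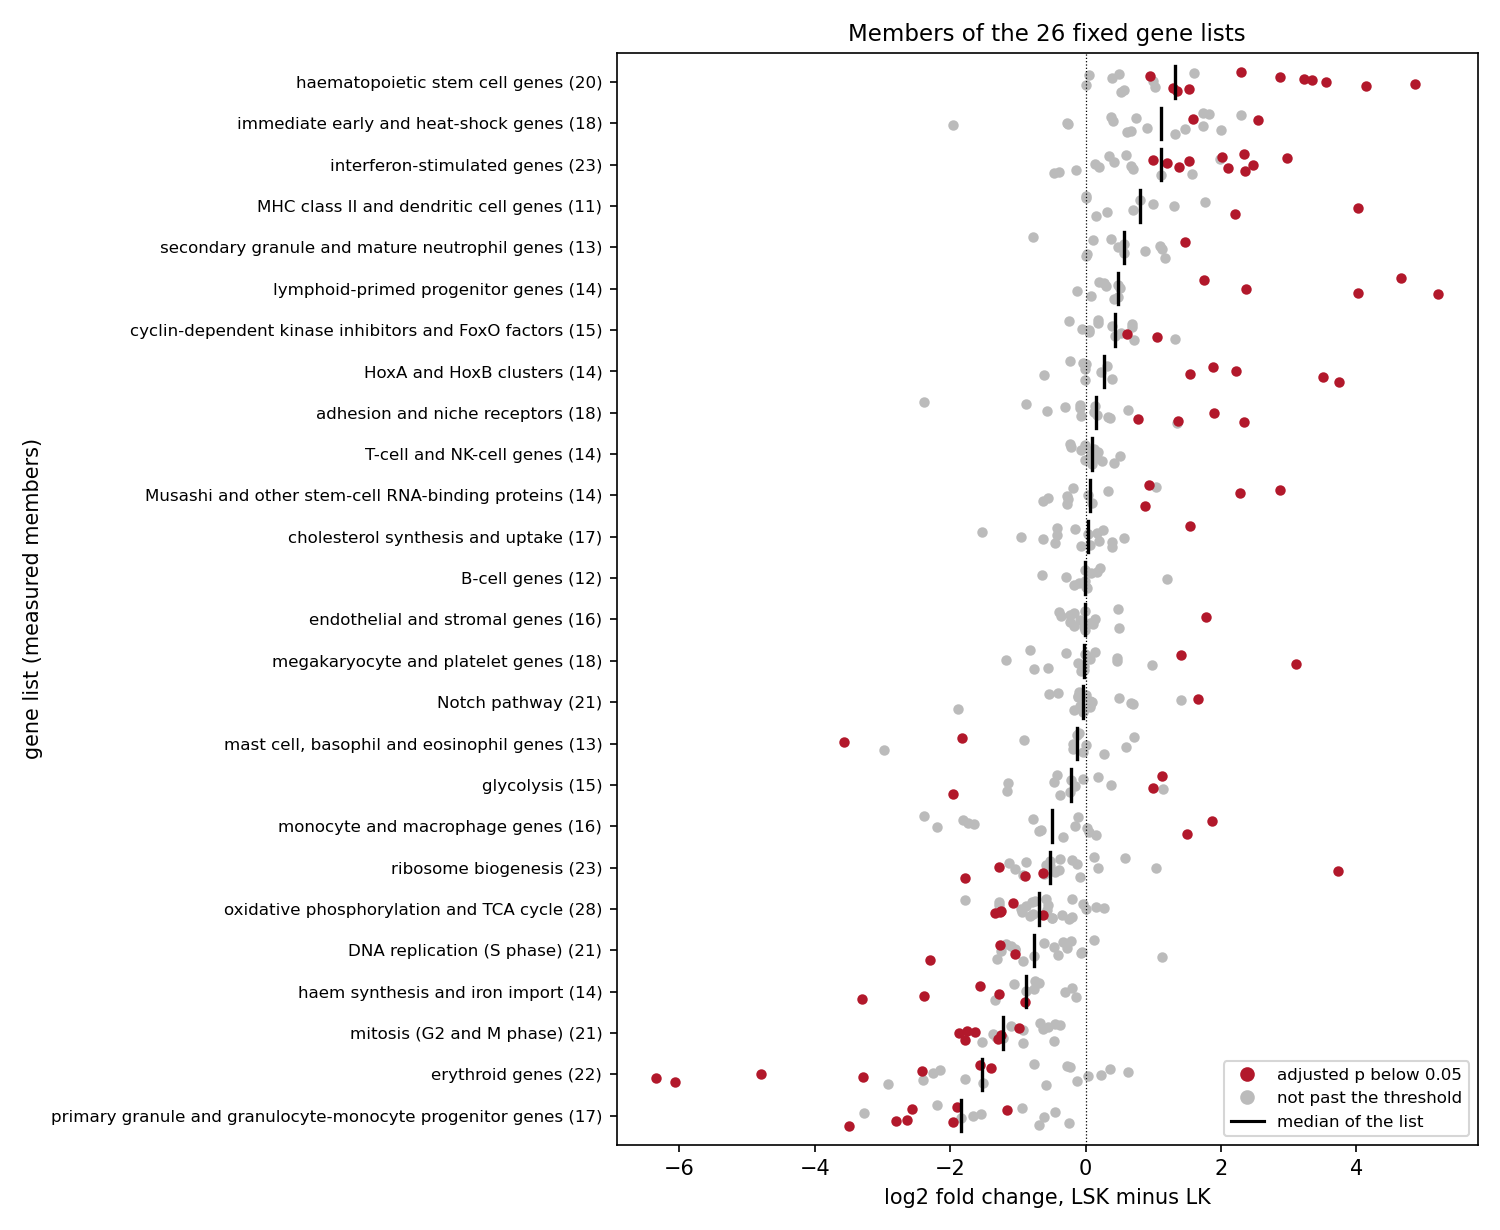
Log2 fold change of LSK minus LK (horizontal axis) for each measured member of the 26 gene lists (vertical axis, with the number of members), ordered by the list's median, with members past an adjusted p of 0.05 in red, other members in grey and the median as a black line. The medians ran from -1.84 for primary granule genes to 1.31 for stem cell genes.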

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

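The tests of Xist, of the interferon-stimulated genes and of neutrophil RNA below were chosen after the values they measure, or values that bear on them, had been seen, and those of other splits of the arrays before.

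Of the 10 splits of the 6 arrays into 3 and 3, 1, the real one, gave as many as its 1225 genes in limma, and the highest of the 9 others gave 0 (162 to 1150 genes at an unadjusted p under 0.05). For the lists, 1 split gave as many as the 16 of the real one, and the 9 others gave 4 to 12 although they called 0 genes. Each other split mixes the populations unevenly, so part of the real difference remains in it. In the fit with the replicate block, 1 of the 4 splits that part all 3 pairs, the real one, gave as many as its 2617 genes, and the highest other gave 0, where the others exchange the populations within 1 pair. So few splits cannot give a share under 0.05.

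A signal outside the comparison stood out in the hybridisation controls, transcripts added to each sample at hybridisation. BioB was higher by 1.01 on the log2 scale on the replicate 2 arrays of both populations than on the other arrays. Among 10092 probe sets that name no single gene, 166 were past the threshold between LSK and LK, 131 higher and 35 lower in LSK.

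Xist, the RNA of the inactive X chromosome, was high in replicates 2 and 3 of both populations (log2 11.27 and 10.38 in LSK, 10.54 and 9.92 in LK) and near the floor in replicate 1 (3.42 and 3.70). The Y-linked gene Eif2s3y was present on all 6 arrays, from 7.70 to 8.41. An array batch marked by the hybridisation controls is argued against, since BioB of replicate 3 differed from replicate 1 by at most 0.064 log2 while Xist differed. Whether cells were pooled from male and female mice in replicates 2 and 3, and from males alone in replicate 1, stays open: the detected Y-linked genes differed from replicate 1 by a median of -0.62 log2, but Kdm5d fell on all of these arrays (-0.79 to -1.58), while Eif2s3y fell in LK (-0.45 and -0.37) and differed by -0.058 and 0.21 in replicates 2 and 3 of LSK. The labels give no sex, and no biological explanation from the design was tested.

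The interferon-stimulated genes were higher in LSK with a median log2 difference of 1.11, and the list's call was lost with an estimated correlation (adjusted p = 0.262). Each number occurs once in each population, so a difference between animals or array batches that both arrays of a number share cancels from the comparison. The pairs are therefore no test of it. The median was above 0 within each of the 3 pairs, at least 0.75. Whether RNA integrity or amplification was the whole cause cannot be decided. With the 3' to 5' difference as a covariate the median was 0.91 (camera adjusted p = 1.34e-10 at the preset correlation). That p carries little weight, since the call without the covariate was lost with an estimated correlation. The covariate also followed the population (correlation of -0.76), so the fit separates their effects poorly. RNA of monocytes in the LSK gate stays open. Of 9 abundant monocyte and macrophage genes 8 were lower in LSK (median -1.65), and Klf4 was 3.66-fold higher. All 9 were over a log2 of 6 in LK, which would hide a small share. C1qb was 2.84-fold higher in LSK but near the floor (log2 3.84 in LSK and 2.34 in LK). C1qa (2.69 and 2.54) and C1qc (2.63 and 2.58) lay at the floor and did not pass the threshold. The sort itself also stays open and is untested: Sca-1 is itself induced by interferon, so a gate on Sca-1 may favour cells with an interferon response.

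Genes of neutrophil granules were abundant in both populations (S100a8 at a log2 of 12.66 to 13.08 in LSK and 12.25 to 13.19 in LK), although the gates select against lineage markers. RNA of mature neutrophils in both gates, in amounts that differ by replicate, cannot be told apart from expression by progenitors. Of 9 detected granule genes 8 were highest in replicate 3 in both populations, but so were 10 of 15 detected primary granule and progenitor genes. Of all detected genes 14.5% were, so both sets lay above that share, and arrays of the same number deviate together. Whether more such RNA in LSK gave the higher level of the list cannot be told apart from expression by LK progenitors, since the shifts with the replicate block spanned 1.95 log2, from -0.78 for Wfdc21 to 1.17 for Camp, and LK progenitors may make some of these genes themselves, which was not tested.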

How the results depend on the processing

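Leaving out both replicate 2 arrays, the 3' to 5' covariate, replicate 2 as a batch and the estimated correlation with the block were chosen after the results were seen. The 1225 genes became 2617 with the replicate block, 2606 with array weights, 2397 with replicate 2 as a batch, 537 without both replicate 2 arrays, 25 with the 3' to 5' covariate (100% higher in LSK), 230 against a 1.5-fold change (79.6%), 37 with the variance of each gene alone (91.9%), and 306 to 1269 with 1 array left out (46.0% to 75.5% of them higher in LSK, against 57.1%). The covariate differs between the populations, so it widened the standard errors (median ratio 1.54), and the variance of each gene alone has few degrees of freedom; for the others the cause was not tested. Msi2 was higher in LSK under all 19 settings, with log2 differences from 1.42 to 2.74 and adjusted p from 8.51e-05 to 0.101; it missed the threshold with the 3' to 5' covariate (1.92, adjusted p = 0.101) and the variance of each gene alone (2.28, adjusted p = 0.067), and spanned 2.17 to 2.45 with 1 array left out. The 16 lists became 0 with an estimated correlation (4 at an unadjusted p under 0.05), 0 with that and the block (4 at an unadjusted p), 14 with fry and 16 to 18 with 1 array left out. The tests with an estimated correlation also have few degrees of freedom. The replicate block ended the call of the adhesion list and brought Kit past the threshold (adjusted p = 0.0185), and changed no other call of a named gene or list.

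Among the named genes and the lists, those that reversed were Msi1 and the direction of the test of 5 lists that did not pass, and the cause was not tested. Of the 1225 genes, 18 changed sign with the highest variance probe sets and 6 with averaged probe sets. Msi1 was at -0.053 after renewed quantile and -0.014 after loess normalisation, and below 0 without LK replicate 1 (-0.15), LSK replicate 2 (-0.057) or LK replicate 3 (-0.039), in leave-one-out values from -0.15 to 0.27. The cholesterol list turned with the replicate block, the dim filter, the highest variance probe sets, replicate 2 as a batch and the estimated correlation with the block, each at a median of 0.030, with array weights (-0.011), without both replicate 2 arrays (-0.13), with the 3' to 5' covariate (-0.38) and without LK replicate 2 (-0.28) or LSK replicate 1 (-0.19). The B-cell list turned with loess (0.0062), array weights (0.015), averaged probe sets, the highest variance and fry (-0.0030 each) and without LSK replicate 3 (-0.086) or LK replicate 1 (-0.030). The megakaryocyte list turned with averaged probe sets (-0.047), without both replicate 2 arrays (-0.028) and without LK replicate 2 (-0.013), the endothelial list without LK replicate 1 (-0.099) or LSK replicate 2 (-0.065) and the monocyte list with the covariate (-0.049). Over all leave-one-out fits, turned or not, the medians spanned -0.28 to 0.22 (cholesterol), -0.086 to 0.070 (B-cell), -0.046 to 0.0084 (megakaryocyte) and -0.099 to 0.022 (endothelial). Low signal over background limits genes near a log2 of 3.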

Other observations

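The gene families and single genes in this part were chosen after the data were examined, and no explanation was tested for them. Genes that share a symbol stem were grouped into 544 families and tested with camera, and 13 passed, 5 toward LSK and 8 toward LK, 10 of them also with the replicate block and 0 with an estimated correlation (lowest adjusted p = 0.986). The last setting has few degrees of freedom for 544 families, so its 0 cannot decide whether they differ. The Gimap family of GTPases of the immune system had the lowest p, with 8 of 8 members above 0 in LSK, 5 past the threshold and a median log2 difference of 1.66 (adjusted p = 5.96e-06). Gimap8 was 24.8-fold higher (adjusted p = 0.000554) and Gimap6 18.1-fold (adjusted p = 0.00513), and the others were Gimap7, Gimap1 and Gimap3 (adjusted p up to 0.0391). Nuclear pore genes of the Nup stem were lower in LSK, 19 of 19 below 0 with 3 past the threshold (Nup205, Nup37 and Nup85), 7 with the replicate block, and a median of -0.59 (adjusted p = 3.68e-05). With 1 array left out, both families passed in all 6 fits. The Gimap genes past the threshold numbered 2 without LSK replicate 1 or LK replicate 3 and 3 without LSK replicate 2 or LK replicate 1, with Gimap1 lost in all fits except that without LK replicate 2 (up to 0.118), Gimap3 in all except those without LSK replicate 3 or LK replicate 2 (up to 0.137) and Gimap7 without LSK replicate 1, LK replicate 1 or LK replicate 3 (up to 0.0694). The Nup genes numbered 1 without LSK replicate 1 or LSK replicate 2 and 0 without LK replicate 1 or LK replicate 3, with Nup205 lost in all fits except that without LSK replicate 2 (up to 0.115), Nup37 in all except those without LSK replicate 3 or LK replicate 2 (up to 0.134) and Nup85 in all 6 (up to 0.0904).

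Among the mitochondrial ribosome genes, the Mrpl stem had a median of -0.40 (41 of 47 below 0, adjusted p = 0.00661) with 0 members past the threshold, 10 with the replicate block and 17 lower at an unadjusted p under 0.05 against 1 higher. The Mrps stem had a median of -0.41 (25 of 29 below 0, adjusted p = 0.0147) with 2 past the threshold, Mrps22 and Mrps18b (adjusted p = 0.0467 and 0.0485), and 7 with the block. The Psmc stem, which includes the proteasome ATPases, had a median of -0.95 (7 of 7 below 0, adjusted p = 0.0147) with 1 past the threshold, Psmc6 (adjusted p = 0.0397), and 5 with the block. Its members were grouped by symbol alone, so not all need be proteasome ATPases. With 1 array left out, the Mrpl and Psmc stems were lost without LK replicate 1 (adjusted p = 0.181 and 0.102), and Mrps without LSK replicate 2, LK replicate 1 or LK replicate 3 (up to 0.241). The Mrpl median was -0.65 without LK replicate 2, and 1 member passed without that array or LSK replicate 3. The Mrps median was -0.24 without LK replicate 1, and its members past the threshold numbered 1 without LK replicate 2 and 0 in each other fit. Psmc members numbered 3 without LSK replicate 3 and 0 in each other fit. Mrps22 was lost in all fits except that without LK replicate 2 (up to 0.15), Mrps18b in all 6 (up to 0.165) and Psmc6 in all except that without LSK replicate 3 (up to 0.127). The Hspa stem of heat-shock proteins had a median of -0.50 (12 of 13 below 0, adjusted p = 0.0198) with 3 past the threshold, Hspa14, Hspa4 and Hspa13 (adjusted p up to 0.0448), and 6 with the block. It was lost without LSK replicate 1 or LK replicate 2 (up to 0.0562), and its members past the threshold numbered 3 without LSK replicate 3 and 0 in each other fit, with Hspa14 and Hspa4 lost in all except that without LSK replicate 3 (up to 0.0943 and 0.123) and Hspa13 in all 6 (up to 0.159). The direction of these 4 stems and of the Gimap and Nup families was kept under renewed quantile and loess normalisation.

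Among single genes lower in LSK, Asns, the asparagine synthetase, was 8.10-fold lower (adjusted p = 0.00982), the mitochondrial folate enzyme gene Mthfd2 2.90-fold (adjusted p = 0.015), Shmt2 2.83-fold (adjusted p = 0.0214) and Psat1 2.00-fold (adjusted p = 0.0224). The proline synthesis gene Aldh18a1 was 3.08-fold lower (adjusted p = 0.0161). The metallothionein gene Mt1 was 13.9-fold lower (adjusted p = 0.0124), beside Mt2 at 35.0-fold. Among genes higher in LSK, the cathepsin inhibitor-like genes Ctla2a and Ctla2b reached 10.3-fold (adjusted p = 0.00537) and 11.8-fold (adjusted p = 0.00189), and the syndecans Sdc1 and Sdc4 17.3-fold (adjusted p = 0.00168) and 12.8-fold (adjusted p = 0.00264). Mycn was 13.2-fold higher in LSK, and its paralog Myc did not pass (log2 intensity of 7.16 ± 0.06 in LSK and 7.61 ± 0.34 in LK, log2 difference -0.45, adjusted p = 0.222). With 1 array left out, Mthfd2 was lost without LK replicate 3 (adjusted p = 0.0705), Aldh18a1 without LSK replicate 1 (0.0694), Mt1 and Mycn without either of these (up to 0.0613 and 0.0605), Shmt2 without LSK replicate 1 or any LK array (up to 0.0803) and Psat1 in each fit except that without LSK replicate 3 (up to 0.0898).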
